A study of Lactococcus cremoris subsp. cremoris MG1363 with 15 samples.

How the data were processed

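In all, 15 samples of Lactococcus cremoris MG1363 were each labelled with Cy3 and hybridised to 1 one-colour array, 7 from culture 1 and 8 from culture 2. Per the labels, RNA was extracted with phenol after the cells were chilled on ice water, and was labelled with random hexamers. Per the file headers, the deposited scanner intensity values were extracted with Agilent Feature Extraction 10.5.1.1, whose processed signal is background-subtracted and not scaled between arrays. The deposited series table holds linear intensity values for 12530 features. Its column medians lay between 7085 and 7124, and within each array its values had the order of the median pixel signal (Spearman rho at least 0.9999), so its scale was linear and normalized between arrays, but the method is not given in the sources used here. It served as an alternative, and it has no rRNA or tRNA probes.

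Control spots were left out, which left 13342 probes, and spots that the scanner software marked as non-uniform outliers, 2 to 173 per array, were set to missing. No spot (0) was saturated. The signal was log2 transformed and the 75th percentile of each array was subtracted. Between the arrays this percentile ranged from 13083 to 29425. Probes had to be well above background on at least 5 arrays, which removed 0 probes. The tag value was the mean of its probes, 5 for 2401 of the 2434 tags.

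The probes are named by locus tag. The reference table of genes was that of strain KW2, with 2360 genes, and 0 of its rows held these tags, so the files do not pair the tags with symbols. None of the 26 gene lists fixed before the data were examined could be measured, and the tests of these lists and the time of the purine synthesis list's rise were not made. The rule for named genes was to give the 8 largest rises and the 8 largest falls late against early that had the same sign in both cultures, the purine synthesis genes and further members of lists, and the 3 largest changes in each direction of the other comparisons. Since the tags have no symbols, only the 2 largest rises, the 2 largest falls and the largest difference in each direction between cultures are named here. The classes of rRNA, tRNA and pseudogene probes, and runs of consecutive tags, were chosen after the values were seen.

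The labels give 1 array per time and no replicate at one time, so windows of the labels' minutes were set before the data were examined. Arrays of 1 culture are successive samples of the same vessel, and only 2 cultures were grown, so p-values measure the spread between arrays within windows. No pair of arrays was identical (0 pairs), and the correlation of tag values between arrays ranged from 0.854 to 0.996. Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with window and culture in 1 fit over all 15 arrays, a natural spline with 3 degrees of freedom, or a mean for each culture and window. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and changes of at least 1 on the log2 scale were also counted. Classes of probes were compared with exact permutation tests.

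The fits were tested on simulated data for all 2434 tags, with 50 tags changed at each size. For late against early they found 74 percent of the tags changed by 1 on the log2 scale and 98 percent of those changed by 2, with 5 false calls. For the comparison of cultures they found 90 percent and 100 percent, with 7 false calls. For the spline they found 28 percent of the tags with a straight trend of 1 over the whole course and 84 percent of those with 2, with 4 false calls. The simulated noise was independent between tags and arrays, and a tag's spread was equal on all arrays. It held no slide effect, no shift of low-signal tags and no link between successive samples of a vessel. These rates therefore hold for such noise and may not carry over to the real arrays.

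Alternatives were scaling by the median, quantile normalization, normexp with an offset of 50 followed by quantile normalization, the series table, other filters on dim probes, the median of a tag's probes, another eBayes setting, other windows, culture or slide in other roles, each culture and slide alone, and each array left out. The mean pixel signal was not used here, and normexp took the median signal in its place. Slide and scan were the same division: slide 1 held 8 arrays, 1 of them of culture 2, and slide 2 held 7.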

Results

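Total RNA of the lactic acid bacterium Lactococcus cremoris MG1363 was measured on 15 one-colour Agilent arrays, 1 array per sample. The cells grew in a chemically defined medium with glucose and a limited supply of hypoxanthine, a purine base, and the series is about activation of the regulator PurR by phosphoribosyl pyrophosphate while purines run out. Culture 1 gave 7 samples between 25 and 101 min, and culture 2 gave 8 samples between 0 and 94 min. The samples were placed in an early window (0 to 37 min), a middle window (48 to 64 min) and a late window (79 to 101 min) of 5 arrays each, with both cultures in every window. The arrays carried 12121 probes for 2434 numbered locus tags, 581 rRNA probes, 231 tRNA probes and 404 pseudogene probes. Between 13337 and 13342 of the 13342 probes were well above background on each array. The number of arrays and the spread within windows limit the precision.

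The late and early windows were compared to find which transcripts had changed once the samples were past the middle of the course. Of the 2434 tags, 349 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 155 higher and 194 lower late, and 46 rose and 46 fell by at least 2-fold. The largest rise was that of llmg_0975, from -3.60 ± 0.61 early to 2.12 ± 0.17 late (mean ± SD of log2 signal relative to the 75th percentile of the array, n = 5 each). With culture in the fit this was a log2 change of 5.70 (SE 1.11), or 51.9-fold, with a limma adjusted p of 0.00553. The tag llmg_0973 rose 48.1-fold, by 5.59 (SE 1.07), with the same adjusted p. These SEs draw on the spread within all windows, and the SD of llmg_0975 in the middle window was 3.10. The largest falls were those of llmg_0139, by -3.81 (SE 0.66) or 14.1-fold lower, with a limma adjusted p of 0.00292, and llmg_0138, by -3.78 (SE 0.64) or 13.8-fold lower, with a limma adjusted p of 0.00274. With each array scaled by its median 142 tags were higher and 263 lower, and with normexp and quantile normalization 195 and 311. The files do not pair locus tags with gene symbols, so no pathway is named.

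**Figure D1:**
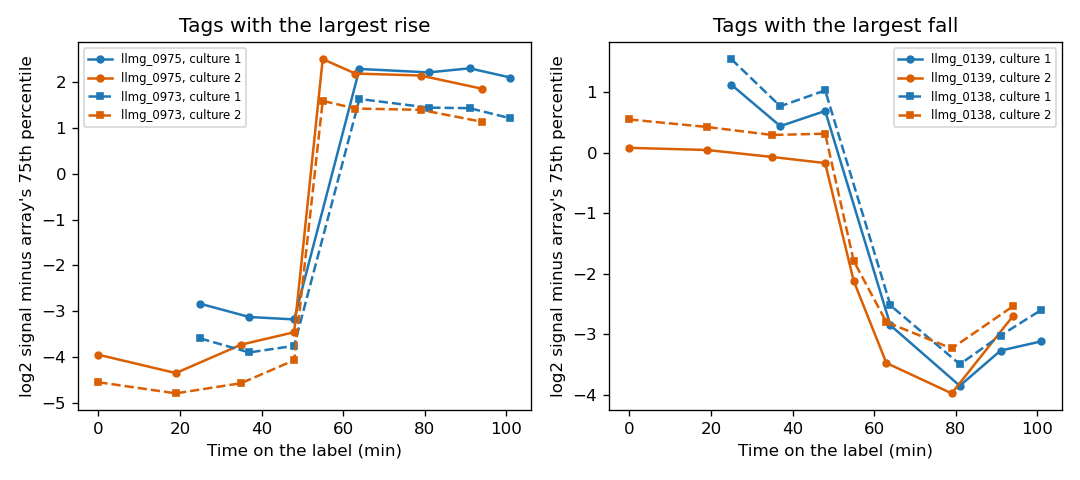
Each point is 1 array, with the minutes on its label on the horizontal axis and the log2 signal minus the 75th percentile of the array on the vertical axis, for llmg_0975 and llmg_0973 on the left and llmg_0139 and llmg_0138 on the right. In culture 2, llmg_0975 lay at -3.46 at 48 min and 2.50 at 55 min, and in culture 1 at -3.18 at 48 min and 2.29 at 64 min.

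Changed tags lay next to each other. Of the 92 tags that changed by at least 2-fold, 62 lay in runs of at least 2 consecutive measured tags that moved the same way, 31 in 9 rising runs and 31 in 10 falling runs. The run that begins with llmg_0973 and includes llmg_0975 held 6 tags, with a mean log2 change of 5.13 and a range of 3.48 to 5.70. A second rising run of 6 tags had a mean change of 3.74, and a rising run of 4 tags had a mean change of 4.73. The longest run held 8 tags, which fell with a mean change of -1.38, and a falling run of 5 tags had a mean change of -1.80. In 10000 shuffles of the tags' order the longest run held 4 tags and at most 19 tags lay in runs. The permutation p was 0.0001 for each, the smallest that the shuffles can give. The shuffles test only a random order of the tags, and runs were chosen after the values were seen.

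The 2 cultures moved alike between the early and late windows. All 349 changed tags had the same sign of change in both cultures, although these tags were chosen on the same arrays. Across all 2434 tags, which are not independent replicates, the late-minus-early changes of culture 1 and culture 2 correlated with a Pearson r of 0.912 and a Spearman rho of 0.858, with no array in common. Late against early, llmg_0975 changed by 5.19 in culture 1 and by 6.01 in culture 2, and llmg_0139 by -4.20 and -3.36. The test of a different change in the 2 cultures called 0 of 2434 tags with limma, against 11 at an unadjusted p under 0.05, and its smallest adjusted p was 0.999. These 11 are fewer than chance alone would give at that threshold. On simulated data this test found 22 percent of tags whose change differed by 1 on the log2 scale and 72 percent of those that differed by 2. The simulated spread was equal on all arrays, so it lacked the difference between the arrays at 48 min and the later middle arrays. For llmg_0975 the SE of the test was 2.38, so that differences well over 2-fold could be missed. The 0 calls therefore do not show that the cultures changed alike.

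With slide in place of culture the late-against-early count was 330, while it was 2 in culture 1 alone and on slide 1 alone and 0 in culture 2 alone and on slide 2 alone. Leaving out culture 1 at 25 min gave 197 tags, at 37 min 219 tags and at 91 min 224 tags, and leaving out culture 2 at 0 min gave 220 tags, and the first 2 against the last 2 arrays of each culture gave 112, 7 arrays up to 48 min against the 8 from 55 min 1306, and 2 alternatives chosen after the values were seen, without both arrays at 48 min and with each array's median shift of its low-signal tags as a covariate (the low-signal covariate), 724 and 582.

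The first large difference between neighbouring samples of each culture came after 48 min. In culture 1, 526 tags rose and 199 fell by at least 2-fold between 48 and 64 min, against at most 5 tags up and 51 down in the earlier intervals. In culture 2, 599 tags were at least 2-fold higher and 97 lower at 55 than at 48 min, against at most 15 up and 76 down in the earlier intervals. Of the 526, 398 lay outside the lowest 10 percent of tags by mean signal, and of the 599, 408 did. The median change of those lowest tags in the same intervals was 1.05 in culture 1 and 1.39 in culture 2 (log2). Among the later intervals of culture 2, the counts were 9 tags up and 518 down from 55 to 63 min, 87 up and 39 down from 63 to 79 min, and 559 up and 0 down from 79 to 94 min. Those of culture 1 were 91 up and 164 down from 64 to 81 min, 27 up and 0 down from 81 to 91 min, and 0 up and 179 down from 91 to 101 min. Of the 559 tags up from 79 to 94 min in culture 2, 356 lay outside the lowest 10 percent, whose median change there was 1.52. The share outside the lowest tags thus does not set the change after 48 min apart from that interval. All of these interval counts are differences between single arrays and carry no test. Culture 2 at 63 min was on slide 1 and the other arrays of culture 2 on slide 2. Its changes from 48 and 55 min and to 79 min therefore cannot be told apart from a difference between slides. From 55 to 63 min the lowest tags also had a median change of -1.28. Across the 2434 tags, the change of culture 1 from 48 to 64 min correlated with that of culture 2 from 48 to 63 min (Pearson r = 0.842, Spearman rho = 0.755). With the change of culture 2 from 48 to 55 min, both on slide 2, the values were r = 0.870 and rho = 0.863. The lowest tags rose in culture 1 from 48 to 64 min and in culture 2 from 48 to 55 min, which adds to that correlation. The levels of the 2 cultures at 48 min correlated with r = 0.984.

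**Figure D2:**
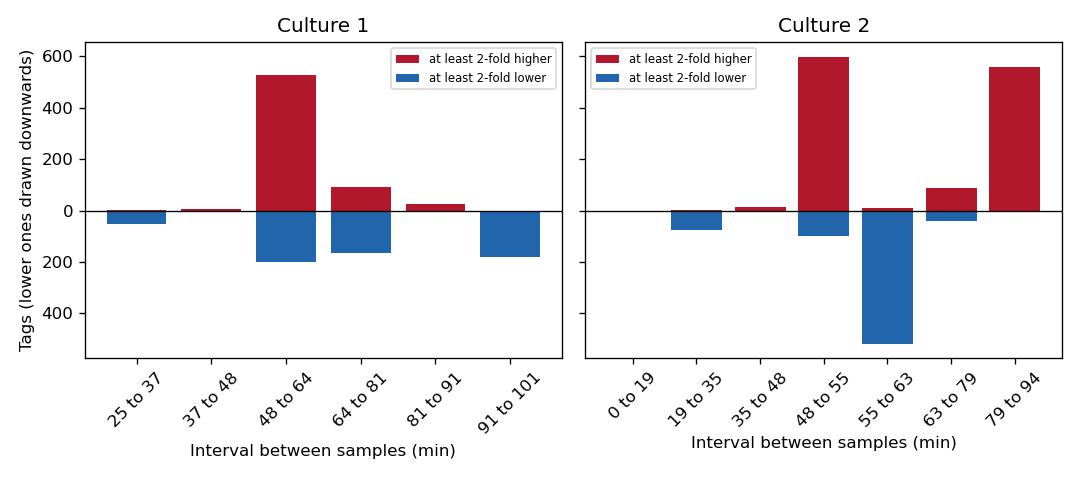
Bars give the number of numbered tags at least 2-fold higher (upwards) or lower (downwards) than in the sample before, for each interval in minutes and each culture, 1 array per sample. The interval from 48 to 64 min in culture 1 had 526 tags up and 199 down, and the interval from 48 to 55 min in culture 2 had 599 up and 97 down, followed by 9 up and 518 down from 55 to 63 min. Culture 2 at 63 min was on slide 1 and the other arrays of culture 2 on slide 2.

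The 46 tags that rose by at least 2-fold were followed over the course. Their mean log2 change from the early arrays of the same culture was 0.0015 ± 0.25 (SD over tags) at 48 min and 2.40 ± 1.78 at 64 min in culture 1, and 0.23 ± 0.17 at 48 min and 2.45 ± 2.03 at 55 min in culture 2. It then stayed between 2.49 and 2.59 at 81 to 101 min in culture 1 and between 2.49 and 2.72 at 63 to 94 min in culture 2. The 46 falling tags were at -1.46 ± 0.76 at 64 min in culture 1 and between -1.86 and -1.51 at 81 to 101 min. In culture 2 they were at -0.88 ± 0.68 at 55 min, -1.63 ± 0.70 at 63 min, -1.71 ± 0.61 at 79 min and -1.25 ± 0.59 at 94 min. On the 55 and 94 min arrays the lowest 10 percent of tags by mean signal were shifted up by a median of 1.16 and 1.05. A later fall in culture 2 cannot be told apart from such differences between arrays. The rising and falling tags were chosen on the same arrays, so the curves describe them and are not independent evidence.

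The middle window was compared with the early one to catch the start of the change. No tag passed the threshold (0 of 2434 with limma, smallest adjusted p 0.141), although 661 had an unadjusted p under 0.05. The tag llmg_0975 had a mean of 0.069 ± 3.10 (SD, n = 5) in the middle window, against 0.61 for the SD of the early window. Both arrays at 48 min lay with the early arrays for this tag. Leaving out culture 1 at 48 min gave 611 tags, leaving out culture 2 at 48 min gave 484, and leaving out both, an alternative chosen after the values were seen, gave 1276 tags, 749 higher and 527 lower.

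The late window was compared with the middle one. It differed at 74 tags (limma adjusted p under 0.05), 43 higher and 31 lower, and 4 rose and 6 fell by at least 2-fold. The middle window holds both arrays at 48 min, so this comparison includes the change after 48 min and does not isolate what changed last. The tag llmg_0139 had a log2 difference of -1.90 (SE 0.66) and a limma adjusted p of 0.139. Its level at 48 min was 0.69 in culture 1 and -0.17 in culture 2. On the later middle arrays it was -2.85 at 64 min in culture 1, and -2.12 at 55 and -3.48 at 63 min in culture 2. The late mean was -3.39. Among 100 splits of the 10 arrays into these 2 windows, 7 gave as many tags, the real one included, so that chance could not be excluded for this count. Scaling each array by its median gave 46 tags, 22 higher and 24 lower, quantile normalization 121, 60 higher and 61 lower, normexp and the values of the series 130 each, 60 higher and 70 lower, eBayes with a trend 117, each culture and slide 1 alone 2, slide 2 alone 0, and the 2 alternatives chosen after the values were seen, without both arrays at 48 min and with the low-signal covariate, 567 and 221. Leaving out culture 1 at 91 min gave 30 tags, at 101 min 37 and at 25 or 37 min 48 each, and leaving out culture 2 at 19 min gave 45, at 35 min 48 and at 79 min 46.

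The minutes themselves, fitted as a spline with 3 degrees of freedom and culture as a covariate, accounted for change at 381 tags (limma F test, adjusted p under 0.05). The tags llmg_0138 and llmg_0139 shared the smallest limma adjusted p of 0.000168, and that of llmg_0975 was 0.000709. A straight line in minutes gave 437 tags, each culture or slide alone gave 0, and the same 2 later alternatives gave 246 without both arrays at 48 min and 862 with the low-signal covariate. Leaving out culture 1 at 25 or 37 min gave 228 and 242 tags, and culture 2 at 0, 19 or 35 min 233, 233 and 232. Cut before and after 55 min, as 7 arrays up to 48 min against 8 from 55 min, the course gave 1306 changed tags, 802 higher and 504 lower later, with 74 and 87 of them at least 2-fold. This was an alternative set before the data were examined. Of the 349 tags of the late-against-early comparison, 306 were among them, and of the 92 with at least a 2-fold change, 90 were.

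The cultures, which the design treats as repeats of 1 experiment, were compared across all windows. In all, 11 tags differed (limma adjusted p under 0.05), 9 higher and 2 lower in culture 2, against 289 at an unadjusted p under 0.05. The tag llmg_0677 was lower in culture 2, with a mean of -8.11 ± 0.42 (SD, n = 8) against -3.13 ± 0.51 (n = 7) in culture 1. The fitted log2 difference of the probe mean was -5.00 (SE 0.24), with a limma adjusted p of 1.01e-08, and is no measure of size, since 4 of the 5 probes were near background in culture 2. The tag llmg_0673 was 11.5-fold higher in culture 2, at -0.45 ± 0.32 (n = 8) against -4.00 ± 0.28 (n = 7), with a limma adjusted p of 8.69e-09. Of the 11 tags, 10 lay within 50 tag numbers of llmg_0677, where 96 tags were measured and 0.434 would be expected by chance, in a region chosen around this tag after the values were seen. Of the 8 tags just before it, 5 passed the threshold, all with higher values in culture 2.

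**Figure D3:**
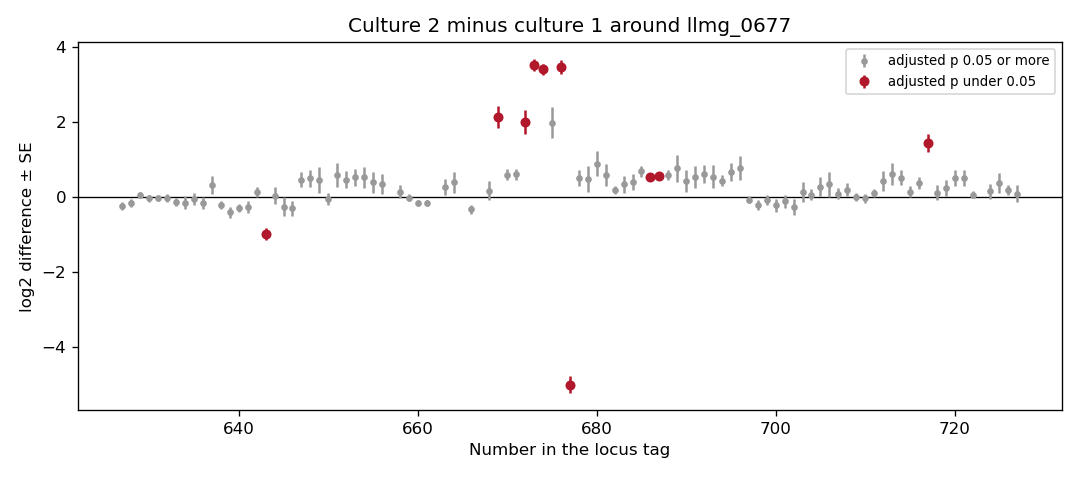
Points give the fitted log2 difference of culture 2 minus culture 1 with its SE, in the order of the number in the locus tag, for the 96 measured tags within 50 numbers of llmg_0677, and red points have a limma adjusted p under 0.05. The tag llmg_0677 lies at -5.00, a probe mean that includes 4 probes near background in culture 2, and llmg_0673 at 3.52.

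The probes of llmg_0677 disagreed. Of its 5 probes, 4 were well above background on all 7 arrays of culture 1 and on 4 of 32 spots in culture 2. For the 2 of them that were well above background on 0 of 8 arrays of culture 2, culture 1 was at least 18.0-fold and at least 15.6-fold brighter. These bounds set culture 1 against the higher of the probe's own signal and the lowest signal well above background on each array of culture 2. The remaining probe had a signal of 34464 ± 6305 (SD, n = 7) in culture 1 and 31334 ± 10548 (n = 8) in culture 2. In culture 1 the other 4 probes had mean signals of 1350 to 2315. A filter that keeps probes well above background on all arrays left the bright probe alone, and the log2 difference of llmg_0677 was then 0.24 (limma adjusted p = 0.420). That filter removes the probes that are dim in culture 2, so this value does not weigh against their difference.

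Slide and culture were nearly the same division of the arrays, apart from culture 2 at 63 min. With slide in the fit, 4 of the 11 tags kept an adjusted p under 0.05, and all 11 kept the sign of their difference, but this rests on that 1 array, which is assumed to vary like the others. The same limit holds for the 7 tags that did not pass, where the median ratio of the difference with slide to that without was 0.787. On slide 1 alone, with 7 arrays of culture 1 and 1 of culture 2, the difference was 3.76 for llmg_0673. Quantile normalization gave 26 tags, 18 higher and 8 lower, normexp 21, 16 higher and 5 lower, and the values of the series 24, 17 higher and 7 lower. In alternatives chosen after the values were seen, 5 tags passed without culture 2 at 55 and 94 min and 33, 29 higher and 4 lower, with the low-signal covariate.

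Stable RNA classes were summarised by the median of their probes relative to the 75th percentile of the array. The tRNA probes lay at 1.62 ± 0.12 early, 1.16 ± 0.51 in the middle and 1.35 ± 0.14 late (log2, mean ± SD, n = 5 each). The late-minus-early difference was -0.27 (two-sided exact permutation p = 0.0159, adjusted to 0.190 over 12 tests of 4 classes, where the smallest possible p was 0.00794), so it did not pass the correction. The lowest tRNA medians were 0.76 in culture 1 at 64 min and 0.46 in culture 2 at 63 min, against 1.46 in culture 2 at 55 min. The rRNA probes lay at 4.21 ± 0.40 early and 3.73 ± 0.25 late (n = 5 each, two-sided exact permutation p = 0.0635, adjusted to 0.254). Their difference was 0.069 in culture 1 alone and -0.97 in culture 2 alone. Before scaling, the rRNA medians of culture 2 were 305372 to 362049 early, and 286636 and 318139 late. The percentile subtracted there was a signal of 15060 to 15517 early, and of 24124 and 29425 late. The tRNA medians of culture 2 before scaling were 44758 to 53770 early, and 57692.5 and 83125 late, so they were higher late. A change of rRNA or tRNA in culture 2 therefore cannot be told apart from this change of the percentile. The late-minus-early difference of the pseudogene probes was 0.22 (n = 5 each, two-sided exact permutation p = 0.278).

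**Figure D4:**
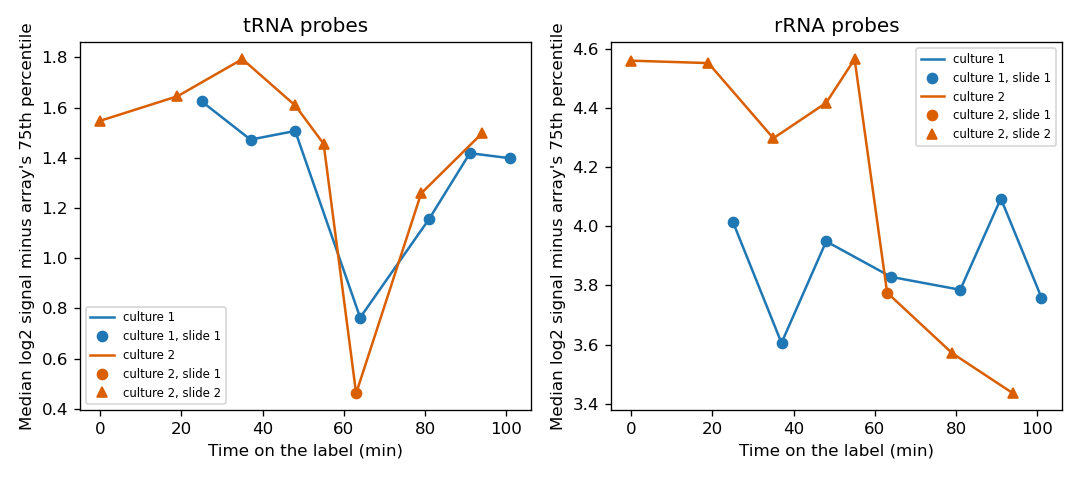
Each point is the median of the tRNA (left) or rRNA (right) probes on 1 array, as log2 signal minus the 75th percentile of the array, against the minutes on the label, with circles for slide 1 and triangles for slide 2. The tRNA medians of 0.76 in culture 1 at 64 min and 0.46 in culture 2 at 63 min are the lowest of the 15 arrays.

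Tags with low signal were higher on some arrays. The 243 tags in the lowest 10 percent by mean signal had a median shift from their own means of 1.16 in culture 2 at 55 min and 1.05 at 94 min (log2), and of 0.56 in culture 1 at 64 min. In the same culture 2 intervals the number of tags at least 2-fold higher was 599 from 48 to 55 min and 559 from 79 to 94 min. Of these 243 tags, 5 were among the 155 that were higher late and 1 among the 194 that were lower. Without culture 2 at 55 and 94 min the late-against-early comparison gave 333 tags, of which 275 were among the 349.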

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

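The settings that leave out culture 2 at 55 and 94 min or both arrays at 48 min, add the low-signal level as a covariate or take the percentile over numbered tags, and all settings for RNA classes, were chosen after the values were seen. The cause of the changes below was not tested, except that fits of 1 culture or slide have fewer arrays. Settings whose fit repeats another are counted once below (such as no filter on dim probes, which repeats the reported fit, and, between windows, slide 1 alone, which repeats culture 1 alone, and slide with culture, which repeats leaving out culture 2 at 63 min). Late against early had a count within 1.5 times in 23 of 34 settings. It gave 2 tags in culture 1 alone and on slide 1 alone, 0 in culture 2 alone and on slide 2 alone, 112 with the first and last 2 arrays, 1306 with the cut at 55 min, 724 without both arrays at 48 min and 582 with the low-signal covariate. Leaving out 1 array gave 197 to 415. The 4 tags named for this comparison kept their sign in all 34 settings and an adjusted p under 0.05 in 31, all but culture 1, culture 2 and slide 2 alone, where it reached 0.287.

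Middle against early gave 0 in 29 of 32 settings, 1276 without both arrays at 48 min and 0 to 611 when 1 array was left out. Late against middle gave 46 with median scaling, 121 with quantile normalization, 130 with normexp and with the series table, 117 with trend and robust eBayes, 221 with the low-signal covariate, 567 without both arrays at 48 min, 2 in culture 1 alone, in culture 2 alone and on slide 1 alone, and 0 on slide 2 alone. Leaving out 1 array gave 30 (culture 1 at 91 min) to 100. Higher tags were 58.1 percent of these calls, but 46.2 percent with normexp and with the series table, 47.8 percent with the median and 49.6 percent with quantile normalization. The spline gave 0 in each culture alone and on each slide alone, 862 with the low-signal covariate, 246 without both arrays at 48 min, and 228 to 506 when 1 array was left out.

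Between cultures the count was 26 with quantile normalization, 21 with normexp, 24 with the series table, 33 with the low-signal covariate, 4 with slide in the fit, 5 without culture 2 at 55 and 94 min, and 8 to 13 when 1 array was left out. Of the 11 tags, 9 were among those called with quantile normalization, where 69.2 percent were higher in culture 2 against 81.8 percent. The filter for all arrays left llmg_0677 only its bright probe and turned its difference to 0.24. The test of a different change in the 2 cultures gave 0 in all 25 settings.

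The tRNA difference stayed negative in 16 of 16 settings, all of which scale the arrays. Before scaling, the tRNA signal of culture 2 was higher late than early. The scaled difference lost its unadjusted exact p under 0.05 with quantile normalization (-0.13) and normexp (-0.12). The same held in culture 1 and on slide 1 alone (-0.22), and in culture 2 and on slide 2 alone (-0.28). There 2 arrays against 3 allow no p under 0.1. The rRNA difference was 0.069 in culture 1 and on slide 1 alone, and it had an unadjusted exact p under 0.05 with the median (-0.55, p = 0.0476), without culture 1 at 37 min (-0.63, p = 0.0238) and without culture 1 at 91 min (-0.57, p = 0.0476). Leaving out 1 array gave -0.63 to -0.39 for rRNA and -0.31 to -0.22 for tRNA. Quantile normalization sets the brightest probes equal, so it says nothing on rRNA.

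Without the culture term (no replicate block) late against early gave 330 tags, and with culture as a random replicate block 349. With slide in place of culture, late against middle gave 89 and the spline 354. The block changed no call count by 1.5 times. The median late-minus-early change of all tags was 0.062, and -0.042 with median scaling. That of middle against early was 0.13, and 0.015 with quantile normalization, and that of culture 2 against culture 1 was 0.086, and -0.054 with median scaling. The lists, the purine list's half-rise times and their alternatives were not run, for want of symbols. Of the 13342 probes, 8 were not well above background on at least 1 array, 4 of them probes of llmg_0677.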

Other observations

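The tests of slide, DNA, background, brightness, nucleic acid mix and scaling were chosen only after the result was seen. The splits of the samples were set beforehand. In 28 groups of named tags and probe classes, 0 had an array far enough from the others to stand out by Dixon's ratio. This ratio looks for a single array. It can miss 2 that lie apart together, such as the tRNA medians of 0.76 and 0.46 in the middle window.

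Other groupings of the arrays were tried 100 times per comparison, the real one included. For late against early, only 1 split, the real one, gave 349 tags and the highest other gave 0. For the cultures only 1 gave 11 and the highest other gave 0. The other splits mix early with late arrays, or the 2 cultures, which widens the spread within their groups. Their counts of 0 show only that the real divisions parted the arrays more than those tried, and do not exclude chance. The splits treat arrays as exchangeable, which successive samples of 1 vessel are not. With 2 vessels a chance difference between vessels cannot be tested. For the spline, 3 of 100 orders of the minutes gave 381 tags or more, and the highest other gave 1412. For late against middle, 7 of 100 gave 74 or more, and the highest other gave 1114, so chance was not excluded. Some other divisions thus parted these arrays further than the windows did, and what they have in common was not tested. Middle against early and the different change in the 2 cultures had 0 tags, which all 100 splits matched.

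The first pattern is the difference between cultures near llmg_0677. With slide in the fit, 4 of the 11 tags stayed past the threshold, but slide and culture cannot be told apart, since only the 1 array of culture 2 on slide 1 separates them. A candidate explanation is a DNA difference between the cultures, such as a loss or rearrangement, and 4 of 32 spots of the dim probes were well above background in culture 2. No DNA was measured, so it cannot be told apart from a difference in transcription, and a difference between the cultures stays open as untested biology.

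The second pattern is the higher signal of low-signal tags in culture 2 at 55 and 94 min. Added background is argued against, since the dim probes of llmg_0677 rose by at most 0.21 percent of the rise of the low-signal probes, whose raw signal was 2565 at 94 min against 719 on the other 6 arrays. Overall brightness is argued against, since the 55 min array had the lowest 75th percentile of signal (13083) and the 94 min array the highest (29425). A more even mix of nucleic acid, such as carried-over DNA, may be the source, since pseudogene probes were higher by 0.62 and 0.63 on the log2 scale. Wider transcription would give the same, so these cannot be told apart here, and the dim probes, which stayed near background, would separate them only if their DNA were known to be present.

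The third pattern is the low tRNA signal in culture 1 at 64 min and culture 2 at 63 min. Both arrays were on slide 1, whose other 6 arrays are all of culture 1, and an effect of the whole slide is argued against for culture 1 at 64 min, which differed from these 6 by -0.67 on the log2 scale (their SD was 0.16). For culture 2 at 63 min, which differed from them by -0.97, slide and culture cannot be told apart, since it was the only culture 2 array on slide 1. The scaling is argued against, since the 2 arrays differed from the other 13 by -0.67 on the log2 scale in the scaling with the smallest difference of 4, where the SD of the others was 0.15. A brief drop of tRNA, between 48 and 81 min in culture 1 and between 55 and 79 min in culture 2, remains a hypothesis. It was found and tested on the same 2 arrays, and RNA recovery by size in these samples was not tested.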
